A study of Rattus norvegicus with 6 samples.

How the data were processed

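Liver RNA of 6 rats, 3 under limited and 3 under aggressive fluid resuscitation, was hybridised to 1-colour Cy3 NimbleGen expression arrays, per the labels' protocols. The deposited table holds 1 intensity per array for each of 19345 RefSeq transcript rows, 7469 with curated and 11876 with predicted accessions. RMA, which corrects background, normalises between arrays and summarises probes, is the tool named in the submitters' processing notes. Its version, the scanner, the annotation release and any filter are not given in the sources used here. The deposited intensities were on a linear scale, between 13.5 and 57240, so log2 was taken before any test. Array medians were 239, 243 and 226 for the limited and 212, 235 and 245 for the aggressive arrays. Signal over background was not given in the sources used here, so 3 arrays per group, and not a known depth, set the precision. Between 19.2% and 20.0% of the values of each array recurred exactly in another array, and 0 pairs of arrays were identical. Arrays correlated at 0.965 to 0.970 within and 0.955 to 0.963 between groups on the log2 scale across rows. The extraction kit differs between the label fields, which name both Trizol and an RNeasy kit.

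Groups and replicate numbers were taken from the sample labels. Unversioned accessions were matched to gene symbols in a RefSeq table of the rat assembly GRCr8. This named 7223 rows with 1 symbol each (7126 distinct symbols), 0 with several, and left 12122 rows, mostly predicted transcripts, unnamed here. The array's build is not given in the sources used here, so no coordinates are printed. Animals without shock were not analysed here.

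Each row was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual and 3.26 prior degrees of freedom), with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. Differences are limited minus aggressive. A looser count took an unadjusted p under 0.05 with a 2-fold difference. Gene lists were tested with camera (preset correlation 0.01, 1 row per gene, the one with the highest mean), adjusted over the 31 of 33 lists with at least 5 measured members. The lists, 22 of pathways and 11 of cell types, held 730 genes, of which 575 were measured, and were written before the data were examined, as were the tests and the rule for named genes. Members were also adjusted over the list alone. Estimated correlations and fry, which tests whether the genes of a set move one way on balance, were alternatives. With an estimated correlation camera also uses the 4 residual degrees of freedom, in place of a number set by the count of genes. A list that did not pass there is therefore not shown to have correlated genes.

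Genes are named by a fixed rule, using 1 row per gene with a symbol other than a locus number. It takes up to 12 genes per direction with the largest differences among those that passed without overlap, places left being filled by the largest differences at an unadjusted p under 0.05 without overlap. It adds the 3 members with the smallest p of each list that passed camera or had at least 2 passing members (4 for the 3 lists with the smallest p), and 8 genes fixed in advance (Hmox1, Il6, Tnf, Hif1a, Vegfa, Cyp7a1, Pck1 and Alb). This gave 60 genes, of which 14 passed and 10 filled places; 1 gene that passed is not reported here by name. Genes named outside the rule are said to be so.

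On simulated data with 19345 rows, the test called 5 of 100 rows changed 2-fold and 59 of 100 changed 4-fold, 0 in the wrong direction, with 7 unchanged rows called. A list shifted by 0.5 on the log2 scale passed camera and 0 of 30 other lists did. The simulated rows were independent of each other, so this does not show how camera's preset correlation performs on correlated genes. Their variance was drawn without regard to intensity, whereas the real count rose from 22 to 570 rows with an intensity trend and robust prior. The simulated shares of rows called need not hold for these data. Alternatives were a second quantile normalisation, centring of arrays, removal of rows below the median mean, an intensity trend with a robust prior, array weights, the replicate number as a block, 1 row or the mean of rows per gene, a 1.5-fold threshold, limma's treat, and each array left out in turn. Leaving out both arrays with lung transcripts, and the alternatives for list members, were added after the data were examined. Figures were drawn with matplotlib 3.10.9.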

Results

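Hepatic gene expression was measured in male Sprague-Dawley rats, 90 to 120 days old, that had been bled by tail amputation, a model of uncontrolled hemorrhagic shock. Ringer's solution, a balanced salt solution, was infused from the time of amputation. The target was a mean arterial pressure of 50 to 60 mmHg under limited resuscitation and of over 80 mmHg under aggressive resuscitation. Livers were collected at 330 min. Each regimen was assigned to 6 rats, and livers of 3 rats per regimen were each hybridised to a 1-colour NimbleGen expression array. Animals without shock were not analysed here, so every value below compares one regimen with the other and none gives a distance from the unbled liver. The 19345 rows of each array were RMA intensities, with array medians between 212 and 245. Of these rows, 7223 were matched to 1 gene symbol. The number of arrays, 3 per group, limits the precision of every value.

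The comparison asked which hepatic transcripts depended on the pressure target. Of 14 named genes that passed the test, 10 were lower after limited resuscitation, among them genes of stress and amino acid catabolism. Nupr1, a stress-induced transcriptional regulator, had an intensity of 3541 ± 296 (SD, n = 3) under limited and 12280 ± 1884 (SD, n = 3) under aggressive resuscitation, a log2 difference of -1.79. Ddit4, an inhibitor of mTORC1 signalling, was 3.29-fold higher under aggressive resuscitation. The amino acid catabolic enzymes Sds (serine dehydratase) and Tat (tyrosine aminotransferase) were 3.16-fold and 2.79-fold higher there. Tat was among the brightest of these rows, at 11940 ± 1100 (SD, n = 3) under limited and 33280 ± 932 (SD, n = 3) under aggressive resuscitation.

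The largest difference among the named genes that passed belonged to Fgf23, a phosphate-regulating hormone, with a log2 difference of -3.68 (SE 0.310). Its intensity was 114 ± 24.8 (SD, n = 3) under limited and 1506 ± 483.5 (SD, n = 3) under aggressive resuscitation. Dio3, the deiodinase that inactivates thyroid hormone, differed by -2.78 on the log2 scale. The matrix metalloproteinase Mmp3 differed by -2.52, and Slc25a25, a mitochondrial ATP-Mg/phosphate carrier, was 4.64-fold higher under aggressive resuscitation. Car4, a membrane-bound carbonic anhydrase that is also abundant in lung, differed by -2.78 and was raised in all 3 aggressive arrays, from 695 to 970 against 101 to 129 under limited resuscitation.

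Passing genes that were higher under limited resuscitation numbered 4. Slc10a2, the apical sodium-dependent bile acid transporter, was 4.55-fold higher, at 247 ± 47.4 (SD, n = 3) against 54.5 ± 11.6 (SD, n = 3). The chemokine Cxcl10 was 3.98-fold higher, at 4989 ± 816.5 (SD, n = 3) against 1249 ± 171 (SD, n = 3). Cck, which encodes the gut hormone cholecystokinin, was 3.88-fold higher, and Hsd17b2, which oxidises sex steroids, was 2.99-fold higher.

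**Figure D1:**
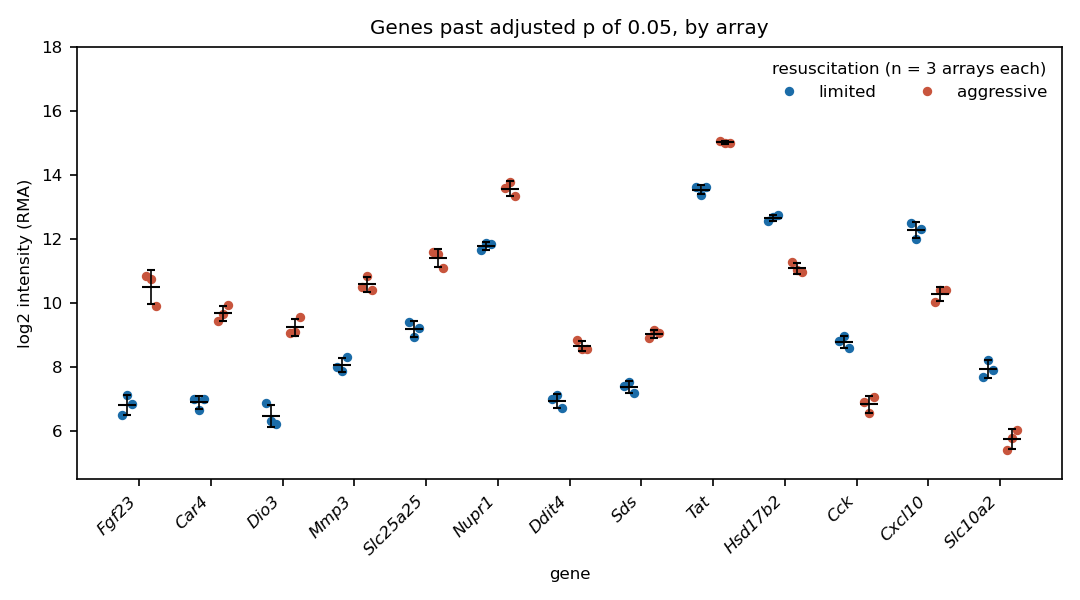
Intensity on the log2 scale (vertical axis) of 13 of the 14 named genes past an adjusted p of 0.05 (horizontal axis), with 1 point per array, the group mean as a dash and 1 SD as the bar. The limited and aggressive arrays do not overlap for any of the 13 genes drawn, of which 9 are lower and 4 higher under limited resuscitation.

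In all, 22 of 19345 rows passed limma's moderated test after Benjamini-Hochberg adjustment, 8 higher and 14 lower under limited resuscitation. The smallest adjusted p was 0.0348, and the adjusted p of the 14 named genes lay between that value and 0.0482. In each of the 22 rows the arrays of the groups did not overlap. Over all rows, 19.8% did not overlap, against 10% by chance. An unadjusted p under 0.05 was reached by 2525 rows, against 967 by chance. Of these, 623 also differed by at least 2-fold, 315 higher and 308 lower. The count of 22 fell to between 0 and 2 when any 1 array was left out, with 2 only without aggressive array 2, and rose to 570 with an intensity trend and robust prior and to 483 without dim rows. Without aggressive arrays 1 and 3, which carried lung transcripts, 3 limited arrays were set against 1 aggressive array. The spread then came from the limited arrays alone, and the lone aggressive array was assumed to vary like them. On that assumption 0 rows passed, and 1582 had an unadjusted p under 0.05.

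Further differences were large but did not pass the adjusted test. Under limited resuscitation, the log2 difference was 1.68 for Cebpa, a hepatocyte transcription factor, 1.63 for Msmo1, an enzyme of cholesterol synthesis, and 1.59 for both Slc40a1, the iron exporter ferroportin, and Gpam, an enzyme of glycerolipid synthesis. It was 1.91 for the transcription factor Snai2, 1.86 for the acyl-CoA synthetase Acsm2, 1.67 for the olfactory receptor Olr1720 and 1.64 for the phosphatase inhibitor Ppp1r1b. Their adjusted p values, with those of the genes before them, lay between 0.0740 (Gpam and Slc40a1) and 0.286 (Olr1720). Snai2, Olr1720 and Ppp1r1b were dim, with limited means of 171, 144 and 122, below the array medians. Gpam, Slc40a1 and Acsm2 lay below the medians under aggressive resuscitation, with means of 89.1, 108 and 97.6, and were also among the rows removed as dim. Olr1720 was 221, 45.3 and 167 in the limited arrays against 33.4 to 40.6 in the aggressive arrays. On the other side were Sftpa1, a surfactant protein, at -3.12 (adjusted p = 0.309, limma), and podoplanin, Pdpn, at -2.52 (adjusted p = 0.150, limma). Sftpa1 followed aggressive arrays 1 and 3, with a difference of -4.58 that passed without array 2 (adjusted p = 0.0212, limma) and of -0.22 against array 2 alone.

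Aggressive arrays 1 and 3 carried lung transcripts, those of surfactant proteins among them, that were low in aggressive array 2 and in the limited arrays. The intensity of Sftpc, surfactant protein C, was 1247 and 1734 in arrays 1 and 3, against 33.7 in array 2 and 30.3 to 57.0 in the limited arrays. Of 17 measured genes on a list of lung genes, 11 were at least 4-fold above the limited mean in both arrays, and 2 of those, Car4 and Pdpn, were so in array 2 as well. The other 9 were Sftpc, Sftpb, Sftpa1, Sftpd, Scgb1a1, Ager, Cldn18, Cldn5 and Lamp3, of which none passed the adjusted test on all 6 arrays. This list, and the genes named from it, were chosen after their values or those of related genes were seen.

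Among cell types, markers of Kupffer cells and macrophages were higher under limited resuscitation by camera (adjusted p = 5.58e-05), but the list did not pass with an estimated correlation (adjusted p = 0.163). All 11 measured markers had a log2 difference above 0, with a median of 0.61, and 6 passed when adjusted over the list alone, while 0 passed over all rows. The colony-stimulating factor receptor Csf1r was 2.17-fold higher, at 3472 ± 309 (SD, n = 3) against 1600 ± 156 (SD, n = 3), and Adgre1, which encodes the macrophage antigen F4/80, was 2.18-fold higher. Cd5l and C1qb were 1.84-fold and 1.74-fold higher. Against aggressive array 2 alone, which lacked the lung transcripts, the median was 0.82, a value that rests on 1 aggressive rat.

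**Figure D2:**
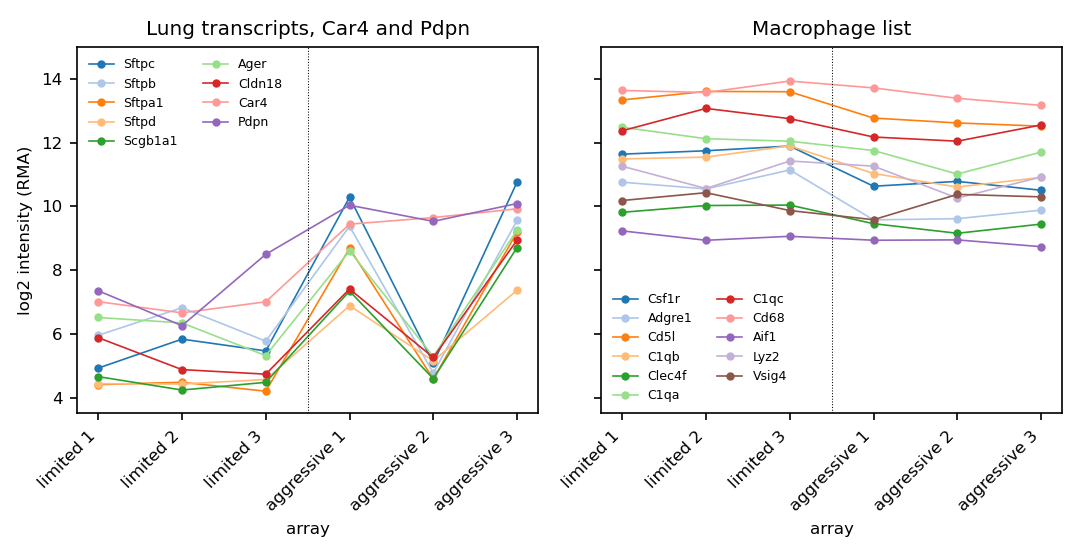
Intensity on the log2 scale (vertical axes) in each of the 6 arrays (horizontal axes) of lung transcripts with Car4 and Pdpn on the left, and of the 11 macrophage markers on the right. Each line joins the values of 1 gene and the dotted line parts the groups. Surfactant transcripts are raised in aggressive arrays 1 and 3 and not in 2, whereas Car4 is raised in all 3 aggressive arrays.

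Immediate early genes, which respond within minutes to growth and stress signals, were lower under limited resuscitation by camera (adjusted p = 5.58e-05), but the list did not pass with an estimated correlation (adjusted p = 0.163). The median log2 difference of 24 members was -0.52, with 19 below and 5 above 0. Over all rows 0 members passed, while 10 lower and 2 higher members passed when adjusted over the list alone. The nuclear receptor Nr4a1 had an intensity of 1047 ± 172 (SD, n = 3) under limited and 2625 ± 311 (SD, n = 3) under aggressive resuscitation. Atf3 was 2.43-fold, Klf6 2.19-fold and Btg2 1.88-fold higher under aggressive resuscitation. Against aggressive array 2 alone, 1 rat without the lung transcripts, the median was -0.28.

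Glucocorticoid-responsive genes were also lower under limited resuscitation by camera (adjusted p = 0.000166), but the list did not pass with an estimated correlation (adjusted p = 0.163). That correlation was -0.043, below the preset 0.01, so correlated genes do not account for the loss, while the fewer degrees of freedom of that setting remain. Of 20 glucocorticoid-responsive genes, whose median was -0.46, 3 passed over all rows (Tat, Sds and Ddit4) and 4 when adjusted over the list alone, all of them lower. The additional gene, Igfbp1, an insulin-like growth factor binding protein made by hepatocytes, was 2.36-fold higher under aggressive resuscitation. The list of gluconeogenesis, glycogen and glucose handling was lower by camera (adjusted p = 0.00741), but not with an estimated correlation (adjusted p = 0.312). Its 20 genes had a median of -0.34, 5 of them above 0, with 4 lower and 1 higher member passing when adjusted over the list alone. Glucose-6-phosphatase, G6pc1, was 2.09-fold higher and the aspartate aminotransferase Got1 1.89-fold higher under aggressive resuscitation. Pck1, the gluconeogenic PEP carboxykinase, had a log2 difference of -0.58 that did not pass (adjusted p = 0.338, limma).

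Hypoxia, unfolded protein and interferon genes also shifted lower by camera's preset test, and none of these 3 lists passed with an estimated correlation. The 24 hypoxia genes had a median of -0.17, and 2 members passed, both lower under limited resuscitation, Ddit4 among them. The demethylase Kdm3a differed by -0.70, Vegfa, the vascular endothelial growth factor, by -0.53 and Hif1a, the hypoxia-inducible subunit, by -0.39, without passing. The hypoxia list passed camera (adjusted p = 0.00609), but not with an estimated correlation (adjusted p = 0.393), by fry (adjusted p = 0.0942) or without aggressive array 2 (adjusted p = 0.0725). Its median depended on the arrays, at -0.29 without limited array 2, -0.28 without aggressive array 1, -0.32 without aggressive array 3 (camera adjusted p = 0.000309) and -0.50 against aggressive array 2 alone, which is 1 rat. For the 16 genes of the unfolded protein and integrated stress response the median was -0.16 and 0 members passed, with Asns at -0.68, Trib3 at -0.59 and Pdia4 at -0.39. This list passed camera (adjusted p = 0.0168), but not with an estimated correlation (adjusted p = 0.393), by fry (adjusted p = 0.0868) or without aggressive array 2 (median -0.08, adjusted p = 0.259). Its median was -0.24 without limited array 2, -0.30 without aggressive array 3 (camera adjusted p = 0.00350) and -0.37 against aggressive array 2 alone.

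The 19 interferon response genes had a median of -0.30, with 2 lower and 1 higher member passing when adjusted over the list alone. Usp18 and Irf7, both induced by interferon, were 2.10-fold and 1.88-fold higher under aggressive resuscitation, whereas Irf1 was 1.86-fold higher under limited resuscitation. The list passed camera (adjusted p = 0.00609), but not with an estimated correlation (adjusted p = 0.393). With the 3 limited arrays set against aggressive array 2 alone the median was -0.24 and the list did not pass (camera adjusted p = 0.0999), with the lone array assumed to vary like the limited ones.

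The list of bile acid synthesis and transport was higher under limited resuscitation by camera (adjusted p = 0.0107), but not with an estimated correlation (adjusted p = 0.362). Of 18 genes, 6 passed when adjusted over the list alone, all of them higher, another 6 lay below 0 without passing, and the median was 0.27. Cyp8b1, the sterol 12-hydroxylase, had an intensity of 9004 ± 1136 (SD, n = 3) against 4240 ± 1105 (SD, n = 3). The sterol transporter Abcg5 was 2.41-fold and the steroid reductase Akr1d1 2.03-fold higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 difference of 0.07, within the spread of the arrays (adjusted p = 0.929, limma).

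In the list of fatty acid oxidation and PPAR-alpha targets, 4 of 26 members passed when adjusted over the list alone, all higher under limited resuscitation, 10 members lay below 0, and the median was 0.12. Angptl4, an inhibitor of lipoprotein lipase, was 2.36-fold higher, the peroxisomal gene Pex11a 1.77-fold and the carnitine palmitoyltransferase Cpt2 1.74-fold. The list passed camera (adjusted p = 0.0190), but not with an estimated correlation (adjusted p = 0.393), nor without dim rows (adjusted p = 0.0559), aggressive array 2 (adjusted p = 0.0563) or aggressive array 3 (adjusted p = 0.137). The median was 0.21 without limited array 3 and 0.19 without aggressive array 1, where the list passed, and 0.27 against aggressive array 2 alone. Of 17 complement genes 1 passed when adjusted over the list alone. The anaphylatoxin receptor C3ar1 was 2.92-fold higher under limited resuscitation, C5ar1 differed by 0.82 and the lectin Mbl2 by 0.61 on the log2 scale. Complement passed camera (median 0.12, adjusted p = 0.0444), but not with an estimated correlation (adjusted p = 0.586), and not without limited array 3 (median 0.04, adjusted p = 0.303), aggressive array 2 (adjusted p = 0.0505) or aggressive array 3 (adjusted p = 0.234). Nor did it pass against aggressive array 2 alone (adjusted p = 0.315), with that array assumed to vary like the limited ones. Its call also ended without dim rows (adjusted p = 0.304), with centred arrays (adjusted p = 0.0669), with array weights (adjusted p = 0.0779) and by fry (adjusted p = 0.0548).

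**Figure D3:**
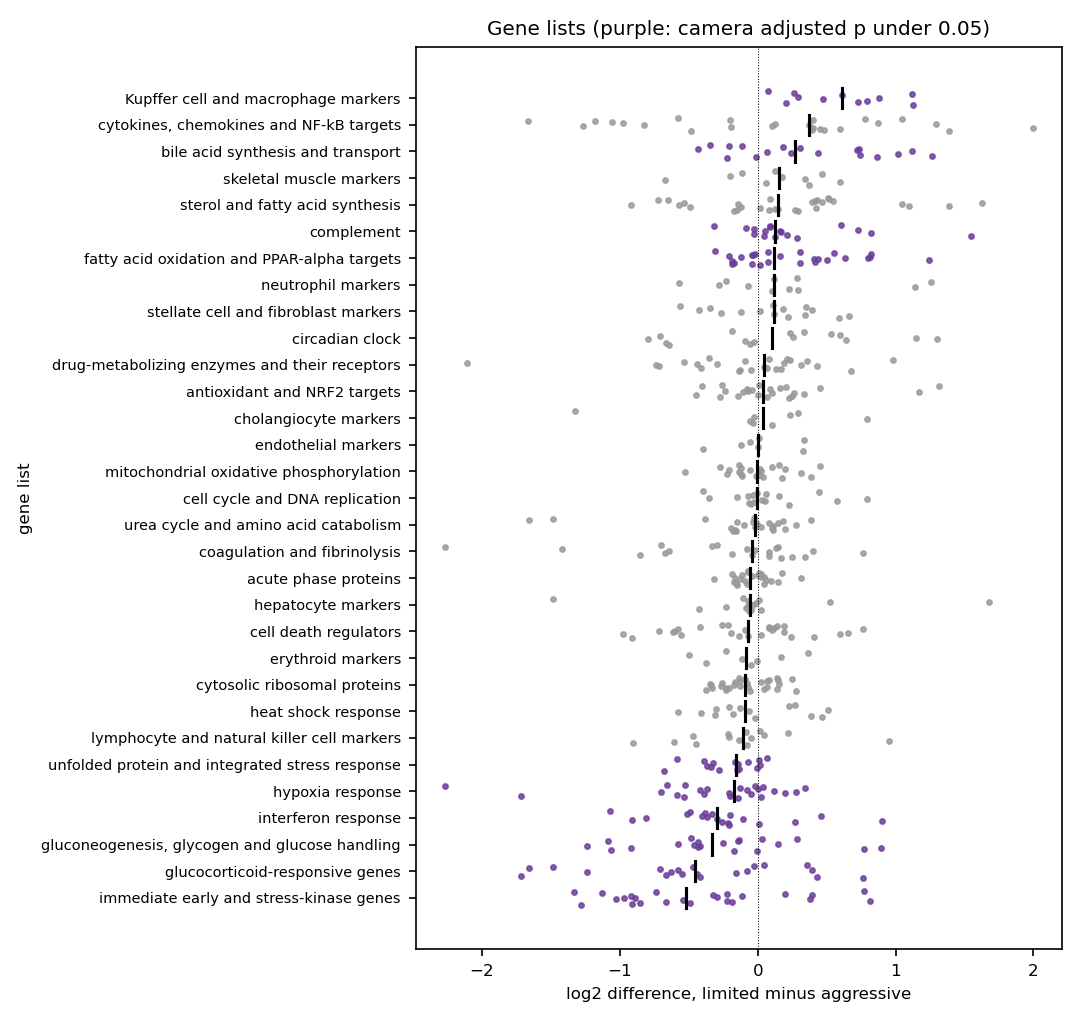
Log2 difference, limited minus aggressive (horizontal axis), of each measured member (point) of the 31 tested gene lists (vertical axis), with the list median as a black bar. Lists in purple, 4 shifted higher and 6 lower, passed camera with a preset correlation. The macrophage markers have the highest median, 0.61, and the immediate early genes the lowest, -0.52.

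The remaining 21 tested lists did not pass camera. Cytokines, chemokines and NF-kB targets split, with 5 higher and 7 lower members of 25 passing when adjusted over the list alone (median 0.37, mean 0.09, camera adjusted p = 0.651). Without limited array 3 the median was -0.11. Tnf, tumor necrosis factor, was 2.07-fold higher under limited resuscitation, at 1008 ± 76.2 (SD, n = 3) against 490 ± 73.1 (SD, n = 3). Il6, interleukin 6, was 2.08-fold higher under aggressive resuscitation but dim, at 43.0 ± 8.76 (SD, n = 3) under limited and 93.8 ± 41.8 (SD, n = 3) under aggressive resuscitation. In the main test both passed only when adjusted over the list alone. With an intensity trend and robust prior, Tnf passed over all rows (adjusted p = 0.00109, limma) and Il6 did not (adjusted p = 0.237, limma). Sterol and fatty acid synthesis had 4 higher and 1 lower member of 29 (median 0.15, adjusted p = 0.245). Its median was 0.26 without limited array 1, 0.24 without limited array 3 and 0.37 against aggressive array 2 alone. The list passed only without aggressive array 1 (median 0.34, adjusted p = 0.0478). Coagulation and fibrinolysis had 1 higher and 3 lower members of 21 (median -0.04, adjusted p = 0.286). In the urea cycle and amino acid catabolism, Sds and Tat were the 2 of 23 members that passed, and Sardh differed by 0.39 (list median -0.02, adjusted p = 0.526). The circadian clock had 2 higher and 1 lower member of 16 (median 0.11, adjusted p = 0.843). Drug-metabolizing enzymes had 1 member on each side of 25 (median 0.05, adjusted p = 0.651), and the antioxidant list had 1 higher of 24 (median 0.04, adjusted p = 0.651).

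In the other pathway lists 0 members passed when adjusted over the list alone. Acute phase proteins had a median of -0.06 over 24 genes (adjusted p = 0.651), heat shock genes -0.10 over 14 (adjusted p = 0.736) and cell death regulators -0.07 over 27 (adjusted p = 0.358). Cell cycle genes had a median of -0.0043 over 17 (adjusted p = 0.667), oxidative phosphorylation genes -0.0031 over 22 (adjusted p = 0.877) and cytosolic ribosomal proteins -0.09 over 29 (adjusted p = 0.352). The heme oxygenase gene Hmox1 had a log2 difference of 0.09 and Alb, albumin, of -0.05, neither beyond the spread of the arrays (adjusted p = 0.901 and 0.946, limma).

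Markers of the remaining cell types did not pass camera. The 16 hepatocyte markers had a median of -0.06 (camera adjusted p = 0.651), with 12 below 0 and with 1 higher and 1 lower member passing when adjusted over the list alone. By fry, which does not compare a list with other genes, they passed (adjusted p = 0.0397). Neutrophil markers had a median of 0.12 over 11 genes, of which 7 lay above 0 and 2 passed as higher when adjusted over the list alone (camera adjusted p = 0.363). Medians were -0.11 for 14 lymphocyte and natural killer markers (adjusted p = 0.443), 0.12 for 15 stellate cell and fibroblast markers (adjusted p = 0.651), 0.04 for 8 cholangiocyte markers (adjusted p = 0.981) and -0.00014 for 7 endothelial markers (adjusted p = 0.881). Erythroid markers had a median of -0.08 over 8 genes (adjusted p = 0.651) and skeletal muscle markers 0.15 over 10 (adjusted p = 0.736). With 1 array left out, medians ran from -0.15 to 0.27 for cholangiocyte, -0.10 to 0.13 for endothelial and -0.15 to 0.08 for erythroid markers. For skeletal muscle markers they ran from 0.02 to 0.35. Platelet and pancreas markers, with 4 measured genes each and medians of 0.10 and 0.13, were too few to test. Median and mean differed in sign for the drug metabolism, cell cycle, endothelial and cholangiocyte lists. Over all lists, 76 of 580 memberships passed when adjusted over the list alone, and 28 did so against aggressive array 2 alone, assumed to vary like the limited arrays.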

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

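Leaving out aggressive arrays 1 and 3, and every alternative for list members, were chosen after the data were examined; the other alternatives were planned. The count of 22 rows past the adjusted threshold was 22 after a second quantile normalisation, 15 after centring and 22 with array weights. It was 483 without dim rows (271 higher, 212 lower, 15 shared with the 22; 9673 rows tested), 570 with an intensity trend and robust prior (302 higher, 268 lower, all 22 shared), and 58 with either 1 row or the mean of rows per gene (23 higher, 35 lower; 7126 tested). It was 0 to 2 with 1 array left out (0 shared with the 22; the 2 without aggressive array 2), 0 without aggressive arrays 1 and 3 (limma; 1582 rows at an unadjusted p under 0.05; the 1 aggressive array left is assumed to vary like the limited arrays, here and below), and 0 with the replicate block (limma; 2196 rows). Fewer arrays or residual degrees of freedom go with the last 3 settings; the cause of the others was not tested. Samples with the same replicate number did not deviate together (correlations across rows of -0.06, -0.05 and 0.05), so the numbers were not taken to pair rats. The 14 passing named genes kept their direction wherever they were tested (3, Ddit4, Cck and Slc10a2, are lost with the dim rows). Their groups did not overlap, so leaving arrays out could not reverse a sign, and the prior and block settings leave the difference unchanged. The kept direction is therefore no separate support. With the trend prior 44 of the 60 named genes passed.

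The count of 623 at 2-fold was 157 without dim rows, 244 with 1 row per gene, 1978 at 1.5-fold, 3 with treat and 990 without aggressive arrays 1 and 3; with 1 array left out it was 618 to 840. Of 10 lists, 0 passed with an estimated correlation and 8 by fry, 7 of them shared and the other the hepatocyte markers; with 1 array left out the count was 6 (without aggressive array 2) to 11, and without aggressive arrays 1 and 3 it was 8. With the replicate block 9 passed, complement being lost (adjusted p = 0.0690). The 76 list members were 124 without dim rows, 159 with the trend prior, 48 (without limited array 1) to 64 with 1 array left out, and 28 without aggressive arrays 1 and 3. The cause was not tested where the number of arrays or rows stayed equal. The medians of the 10 called lists kept their sign in each setting run; signs of the other 8 called rows and of the 76 list members were not compared.

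The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 22 rows, 623 rows at 2-fold, 10 lists and 76 list members, and the highest of the others gave 0, 373, 3 and 0; in each case 1 split, the real one, was as large. With the trend prior, the real split gave 570 rows and the highest other 0, and without dim rows 483 and 0. Intensity relative to background is not given in the sources used here, so which dim rows lie at background is unknown.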

Other observations

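All explanations below were tested after the patterns had been seen, and the genes named in the next 2 paragraphs outside the fixed rule were chosen after their values were seen.

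Inflammatory genes did not move as a block. When adjusted over the list alone, the chemokine Cxcl10, Tnf, Il18, Il1b and Ccl5 were higher under limited resuscitation. In the other direction, the inducible nitric oxide synthase Nos2 was 3.17-fold higher under aggressive resuscitation, at 1712 ± 238 (SD, n = 3) under limited and 5487 ± 1153 (SD, n = 3) under aggressive resuscitation. The chemokine Cxcl9, which like Cxcl10 binds the receptor Cxcr3, was 2.40-fold higher under aggressive resuscitation, opposite to Cxcl10. The interleukin 1 receptor antagonist Il1rn was 1.97-fold and the cyclooxygenase Ptgs2 2.26-fold higher there. Of these genes, Cxcl10 alone passed over all rows in the main test, which used no intensity trend.

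Sterol synthesis split as well. Hmgcs1, an early enzyme of the mevalonate pathway, was 2.62-fold higher under limited resuscitation, and Idi1 2.14-fold, while Insig1, which retains the sterol-regulated transcription factors in the endoplasmic reticulum, was 1.89-fold higher under aggressive resuscitation. All 3 passed when adjusted over the list alone and not over all rows. In the list of coagulation and fibrinolysis, which did not pass camera (adjusted p = 0.286), Procr, the endothelial protein C receptor, was 2.68-fold and thrombomodulin, Thbd, 1.63-fold higher under aggressive resuscitation, and Klkb1, which encodes plasma prekallikrein, 1.70-fold higher under limited resuscitation, when adjusted over the list alone. The cytochrome Cyp3a9 was 4.31-fold higher under aggressive resuscitation, when adjusted over the list of drug-metabolizing enzymes alone.

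Lung transcripts in aggressive arrays 1 and 3 may come from lung tissue in those samples: over 9 measured lung genes whose values had not been seen when they were listed, the elevation above the limited mean correlated between arrays 1 and 3 at 0.876 across genes, which are not independent replicates, but 3 of the 9 were raised at least 4-fold in both, short of the 5 set for the test. That test had first been written for all 17 measured genes, where the correlation was 0.933 and 11 were raised. It was narrowed after these values were known, because 8 of the 17 had drawn attention to the pattern. On the narrower set it does not settle the source. Of the 9 genes there, Napsa, Slc34a2 and Hopx already had limited means of 1055, 811 and 590. A small share of lung RNA need not raise such levels 4-fold. High limited levels do not account for Aqp5, Foxj1 and Clic5, also among the 9, with limited means of 71.5, 44.3 and 76.1. In array 1 these genes reached 82.8, 40.4 and 142, less than 4-fold above those means. In array 3 Aqp5 and Clic5 were raised 4.84-fold and 6.39-fold, while Foxj1 reached 63.35. Bright genes may thus account for only part of the shortfall, and the test leaves the source open. Over all 7126 genes, 13 were raised at least 4-fold in arrays 1 and 3 and less than 4-fold in 2. Of these 13, 9 were on the lung list, although part of that list was chosen from such values. Cyp3a9 and Zfyve27, also among the 13, reached 1764 and 1469 in array 2 against at most 667 and 604 in limited arrays. By the same measure, 2 genes were raised in arrays 1 and 2 and not 3, and 1 in arrays 2 and 3 and not 1. A response of these livers to resuscitation stays open too, since the raised lung genes had a median elevation of 0.0936 in array 2, which is 1 rat. Dilution by lung RNA as the source of the 8 rows higher under limited resuscitation would lower hepatocyte markers in aggressive arrays too. These had a median of -0.0597, which argues against dilution, although a fall may be compressed in bright rows such as Alb (47430 limited, 49390 aggressive). Against array 2 alone, 1 rat without the lung transcripts, Slc10a2, Cck, Cxcl10 and Hsd17b2 still differed by 2.14, 2.24, 1.88 and 1.65 (log2). The 14 lower rows were raised by at least 1.45 in array 2 (log2), which as 1 array excludes nothing.

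Macrophage markers passed camera as higher under limited resuscitation, but not with an estimated correlation (adjusted p = 0.163), and 0 of them passed over all rows. A smaller share of hepatocytes would raise the markers of other cells alike. Macrophage markers exceeded those of lymphocytes, endothelium, stellate cells and cholangiocytes by 0.61 (SE 0.127, over 11 and 44 genes). Genes are not independent replicates and many comparison markers were dim, so this does not settle that explanation. Without dim rows 11 macrophage, 5 endothelial and 9 stellate markers stayed, with too few lymphocyte and cholangiocyte markers for a test. The score of the comparison markers was also uneven, at -0.0628, -0.1154 and 0.1997 in aggressive arrays 1, 2 and 3. Neutrophil markers, left out of the comparison, had a mean of 0.21. Whether macrophages were more numerous or held more of these transcripts cannot be told apart in bulk RNA. The SD over the markers was 0.37, which sets no bound on either. The macrophage list shares 0 genes with the other lists.

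Clock genes differed in opposed directions, although the list did not pass camera (adjusted p = 0.843) and 0 members passed over all rows. When adjusted over the list alone, Dbp and Nr1d1 passed with log2 differences of 1.30 and 1.15, and Nfil3 with -0.79. Bmal1, at -0.67, and Per1, at -0.71, did not pass, and the sign of 12 of 14 genes placed in an arm (not Per1 and Bhlhe41) was that of a shift in clock phase, while Bhlhe40 and Wee1, the others of the 16 measured, were placed in neither arm and lay below 0. A phase score was -1.05 ± 0.137 (SD, n = 3) under limited and -1.87 ± 0.325 (SD, n = 3) under aggressive resuscitation, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. An effect of resuscitation on the clock and a different time of day at sampling cannot be told apart, since no label gives clock times.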
